A study of Paralichthys lethostigma with 45 samples.

How the data were processed

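RNA sequencing was done on livers and spleens of southern flounder juveniles from 2 experiments, which the labels call High and Low. In each experiment fish were left unexposed, kept on sediment mixed with Macondo oil for 8 days, bathed with the bacterium Vibrio anguillarum, or given both. The labels give 57.432 mg/kg oil and 9.03 (in units of 1e5 cfu/mL) bacteria in the High experiment, and 28.501 mg/kg and 4.27 in the Low experiment. Samples were grouped by tissue, experiment and exposure as the labels state them, which gave 16 groups with 2 or 3 libraries each (45 in all, 23 from liver and 22 from spleen). The labels do not say whether a library came from 1 fish or a pool, whether a liver and a spleen came from the same fish, or whether libraries of a group shared a tank, so the independence of the replicates is not known.

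The deposited files hold raw counts per gene, as whole numbers: the authors list exon reads, intron reads and exon junction reads of each gene, for uniquely placed reads and for all reads. Per the labels, RNA was extracted with a Qiagen RNeasy kit, libraries were made with the Illumina TruSeq stranded polyA kit, and CASAVA and FastQC were used, with no version given. The aligner, the counting program and the genome build are not given in the sources used here. The genes lie on reference scaffolds whose species and build are not stated, so no positions are given. Each file lists 24665 genes, of which 10102 (41%) have a symbol and 14563 have only an identifier beginning with LOC. No table of names for those identifiers was at hand, so they were not given names. The spleen files list no exons for 1552 genes that have exons in the liver files, among them 1066 long noncoding RNA genes, 469 tRNA genes and 13 protein-coding genes of the mitochondrion. Those genes were therefore outside the exon counts of the spleen; 412 of the long noncoding ones were tested there by total gene reads alone.

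Total exon reads per gene were used as deposited. Exon reads per library, in units of 1e6, ran from 14.3 to 23.1 in the liver (median 17.3) and from 2.84 to 20.1 in the spleen (median 14). A gene with 0 counts in 1 library could have held up to 3 counts, which corresponds to 0.13 to 0.21 counts per 1e6 counts (CPM) in the liver libraries and 0.149 to 1.06 CPM in the spleen libraries. Such floors and the counting intervals cover counting error only, since reads were not marked by molecule. Replicates varied far beyond counting error, with a chi-square per degree of freedom of 37.4 to 814 between libraries of a group.

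Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr on the groups with its minimum count of 10, TMM scaling, 1 quasi-likelihood fit per tissue with 1 mean per group, and Benjamini-Hochberg adjustment over the genes tested, with a gene called at an adjusted p below 0.05. The filter left 16346 genes in the liver and 18282 in the spleen. The biological coefficient of variation was 40.3% in the liver and 53.9% in the spleen. Each exposed group was compared with the controls of its own tissue and experiment. The interaction contrast asked whether the combined exposure differed from the sum of both single exposures on the log scale. A further contrast took the difference of an exposure's effect between the High and Low experiments. A fit over both tissues (18856 genes) tested the difference of each effect between liver and spleen. Standard errors (SE) of log2 fold changes are those implied by the quasi-likelihood F test. Means are CPM after TMM scaling with the SD over libraries. Where 1 group had 0 counts, the fold is a lower bound against 3 counts over the group. Where a group had 1 to 3 counts, the ratio of counts is given with its exact 95% binomial counting interval.

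The comparisons, the genes to be named and the gene lists were fixed before the data were examined. Against controls, the named genes were the 8 with the largest rise and the 8 with the largest fall among called genes with a symbol, a mean log2 CPM of at least 1 over the tissue and no overlap between the exposed and control libraries. For interactions and differences they were the 3 largest each way. Up to 4 members of each list with the smallest adjusted p were named too. Of the textbook markers fixed for naming, cyp1a, saa and c3 have no symbol in the files, and hamp does. Identifiers without a symbol that are named below were chosen after their values were seen.

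The 21 lists covered aryl hydrocarbon receptor targets, antioxidant and phase II genes, acute phase genes, complement, cytokines and their regulators, pattern recognition, interferon response, antigen presentation, lymphocytes, phagocytes, erythroid cells, thrombocytes and endothelium, chaperones and endoplasmic reticulum stress, sterol synthesis, lipid and bile genes, carbohydrate metabolism, cell cycle, reproduction, hepatocytes, exocrine pancreas, and muscle and gut. Many members have no symbol in the files, so lists are short. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with the correlation estimated from the data, and with fry. Adjustment ran over the lists of a contrast. Member counts are given over all genes tested and adjusted over the list alone. A few false matches of symbols (hpd and cpd in the acute phase list, for example) were left out after the first gene fits had been seen and before any list was tested.

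The alternatives fixed beforehand were DESeq2 1.42.0 with its own size factors, RLE scaling in edgeR, no filter on low counts, the replicate number as a block, only the samples of the same experiment, and leaving out each replicate in turn. Those planned for normalized values did not apply, since the files hold counts. Chosen after seeing the data were marker covariates (mean log2 CPM of gut, hepatocyte and exocrine pancreas members in the spleen, and of exocrine pancreas members in the liver) and a spleen fit of the 14 libraries whose gut members fabp2, cdh17 and slc15a1 summed to at most 100 CPM. The method was tested on simulated data with the real library sizes and dispersions, in which 100 genes were changed 4-fold and 100 were changed 2-fold in each comparison. Between 28% and 58% of the 4-fold changes and between 0% and 9% of the 2-fold changes were called, with 0 to 5 false calls.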

Results

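The data are counts of RNA sequencing reads per gene in livers and spleens of juvenile southern flounder, a bottom-living flatfish. The question the labels state is how oil in sediment, a bath with the fish pathogen Vibrio anguillarum and both together change gene expression in these tissues. Liver groups held 3 libraries each, except the Low controls with 2. Spleen groups held 3 libraries each, except Low oil and Low pathogen with 2 each. Exon reads, in units of 1e6, ran from 14.3 to 23.1 per liver library and from 2.84 to 20.1 per spleen library. Group means below are CPM ± SD, with n = 3 unless stated, and log2 fold changes are given ± SE. By the rule for naming, all exposed libraries lay on 1 side of all control libraries for genes named among the largest changes against controls.

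**Figure D1:**
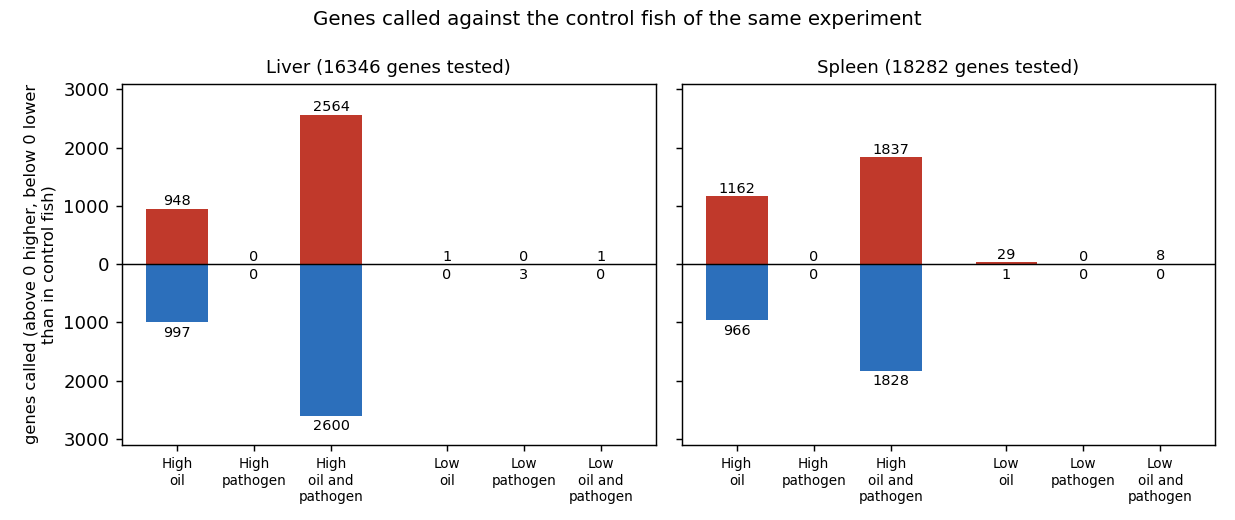
Number of genes called higher (above 0) or lower (below 0) than in the control fish of the same tissue and experiment, for each exposure. The High oil and the High combined groups had 1945 to 5164 called genes, and the other groups had 0 to 30.

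In livers of High oil fish, tiparp, 4 of 14 antioxidant and 12 of 18 cell cycle genes were higher than in control livers, and 4 of 8 phagocyte, 3 of 4 pancreatic enzyme and 2 of 9 complement genes were lower, in lists that lost their calls with an estimated correlation (adjusted p = 0.24). The gene tiparp, a target of the aryl hydrocarbon receptor, the sensor of many oil compounds, rose from 7.35 ± 2.38 to 57.5 ± 14.6 CPM (log2 fold change 2.97 ± 0.35, adjusted p = 0.000207). It was 1 of 2 tested members of its list; the other, foxq1, had 0 counts in controls and did not pass (adjusted p = 0.0633). Of 14 antioxidant and phase II genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), among them gclm (2.67 ± 0.32) and gclc (1.6 ± 0.31), both subunits of the enzyme that begins glutathione synthesis, and gsr (1.28 ± 0.28), which recycles glutathione. That list was higher by camera (adjusted p = 0.0193; adjusted p = 0.24 with an estimated correlation). Of 18 cell cycle genes 12 rose and none fell (17 rose adjusted over the list alone), with a median log2 fold change of 4.7. The mitotic activator cdc20 went from 0.119 ± 0.0803 to 12.9 ± 3.58 CPM (6.62 ± 1.42), and mcm4 of the replication helicase from 0.313 ± 0.148 to 12.6 ± 12.5 CPM (5.24 ± 1.07). The kinase aurka had 0 counts in control livers and was at least 69.2-fold higher. Cyclin B1, ccnb1, had 2 counts in all 3 control libraries and a count ratio of 408 (95% counting interval 113 to 3370). Camera put the cell cycle list higher (adjusted p = 2.07e-10; adjusted p = 0.24 with an estimated correlation).

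Other large rises in these livers were grik2 (7.52 ± 1.3), cdca3 (6.21 ± 1.6) and the low-count genes ncapg2, dlgap5 and plk1, which had 1 or 2 counts in the controls together. The largest fall was that of gck, glucokinase, from 1720 ± 2550 to 1.29 ± 1.34 CPM (log2 fold change -10.4 ± 1.93, adjusted p = 0.00482), with controls that differed widely. The gelatinase mmp9 (-4.77 ± 0.93), cpa6 (-4.32 ± 0.86), add2 (-4.26 ± 0.87), fam117a (-4.1 ± 1.05), acss2 (-3.87 ± 1.02), which makes acetyl-CoA from acetate, fam78a (-3.81 ± 0.79) and gramd2 (-3.59 ± 0.64) also fell. Of 8 phagocyte genes 4 fell (6 adjusted over the list alone), and of 7 lymphocyte genes 4 fell and 1 rose (5 and 1 adjusted over the list alone). The B-cell receptor subunit cd79b had 0 counts in the oil livers and was at least 33.6-fold lower, but the summed CPM of the lymphocyte members was 34.6 ± 7.5 with oil and 29.5 ± 2.26 in controls. Both lists were lower by camera (adjusted p = 9.54e-05 and 0.00689; adjusted p = 0.24 for both with an estimated correlation). Of 9 complement genes 2 fell (7 adjusted over the list alone): serping1, the inhibitor of C1, from 4690 ± 773 to 1760 ± 412 CPM, and c8b from 1430 ± 52.2 to 675 ± 84.1 CPM (list adjusted p = 0.000152; adjusted p = 0.24 with an estimated correlation). Of 4 exocrine pancreas genes 3 fell (4 adjusted over the list alone): cpa1 (-2.24 ± 0.58), ctrl (-2.15 ± 0.58) and cpb1 (-1.98 ± 0.54), digestive enzymes (list adjusted p = 0.000806; adjusted p = 0.24 with an estimated correlation). Summed exocrine pancreas CPM were 33600, 17600 and 26000 in the control livers and 5530, 2110 and 10500 in the oil livers.

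In the same comparison the mitochondrial chaperones hspd1 (1.88 ± 0.4) and hspe1 (1.42 ± 0.35) rose, and hsp90ab1 (-1.1 ± 0.29) and pdia3 (-1.18 ± 0.36) fell, the 4 called of 17 chaperone genes. Erythroid (0 rose, 2 fell of 7) and thrombocyte and endothelium genes (0 and 2 of 5), the muscle and gut list (0 and 1 of 5) and antigen presentation (0 and 1 of 4) had few calls. Cytokine, lipid and bile, and carbohydrate lists each had 1 member up and 1 down, with the gluconeogenic gene pck1 the member that rose in the last (5.45 ± 1.67). No member of the acute phase, pattern recognition, interferon, sterol synthesis, hepatocyte or reproduction lists was called. In all, edgeR called 1945 of 16346 genes, 948 higher and 997 lower. Leaving out 1 library gave 504 (oil 2), 755 (control 2), 763 (control 1), 919 (control 3) and 1093 (oil 3) genes. DESeq2 called 3076 genes, and 57 were called with the exocrine pancreas score as a covariate, which was chosen after seeing the data.

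In livers of High pathogen fish no gene passed the test (edgeR 0 of 16346, 1803 at an unadjusted p below 0.05; DESeq2 284). The 3 livers differed: tnfaip3, an inhibitor of NF-kB signalling, was at 97.1, 13.8 and 5.56 CPM, and hamp, the iron hormone hepcidin, at 5940, 1930 and 650 CPM (hamp control mean 511 ± 403). The camera test put the cell cycle (median log2 fold change 3.36, adjusted p = 5.18e-07), chaperone (1.32, adjusted p = 2.55e-05) and sterol synthesis (1.93, adjusted p = 0.00215) lists higher and the hepatocyte list lower (-0.66, adjusted p = 0.00965). With an estimated correlation these 4 had adjusted p = 0.799, 0.799, 0.824 and 0.799. No member of any list was called over all genes; adjusted over the list alone 14 cell cycle, 8 chaperone and 2 cytokine genes were higher and 1 chaperone gene lower. Leaving out 1 library gave 4 (pathogen 2) and 2 (pathogen 3) genes. Without a filter on low counts 1 gene was called, and 2 with only the High livers in the fit.

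In livers of High fish given oil and pathogen, 4 of 8 cytokine genes and single genes of gluconeogenesis and stress were higher, and 3 of 7 hepatocyte genes and single genes of metabolism were lower, with no list past camera. The gene pck1, which sets the rate of gluconeogenesis, went from 0.763 ± 0.839 to 863 ± 177 CPM (log2 fold change 10.07 ± 1.99, adjusted p = 0.00139), the glycolytic regulator pfkfb3 from 10.1 ± 16.1 to 1820 ± 298 CPM (7.48 ± 2.02, adjusted p = 0.00961) and the stress transcription factor atf3 from 1.06 ± 1.05 to 158 ± 21.4 CPM (7.31 ± 1.63, adjusted p = 0.00307). Further large rises were those of crem (8.03 ± 1.66), a transcription factor of cAMP signalling, arf4 (7.75 ± 2.08), troap (6.89 ± 0.76), ccnb1 and aurka, the last at least 29.6-fold. Of 8 cytokine genes 4 rose and none fell (4 adjusted over the list alone): tnfaip3 (5.44 ± 1.23), socs3 (5.14 ± 1.23), which damps cytokine signalling, ptgs2 (4.79 ± 1.25) and stat3 (1.62 ± 0.37). That list did not pass camera (adjusted p = 0.135) and passed fry, which does not compare it with other genes (adjusted p = 0.0458). The gene tiparp was again higher, at 40.7 ± 13.9 CPM (2.47 ± 0.34), and so were gclm (1.75 ± 0.31) and gsto1 (2.42 ± 0.52), while mgst1 fell (-4.14 ± 0.62). Of 14 antioxidant genes 3 rose and 3 fell (5 and 3 adjusted over the list alone), and that list did not pass camera (adjusted p = 0.745).

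The genes cntn1 and ubap1l had 0 counts in these exposed livers and were at least 102-fold and 90.5-fold lower. Other large falls were cdca7l (-6.52 ± 0.95), fam117a (-6.44 ± 1.28), phospho1 (-6.41 ± 0.63), nr6a1 (-6.2 ± 1.05), haao (-6.17 ± 0.87), an enzyme of tryptophan breakdown, and mogat2 (-5.94 ± 1.01), an enzyme of triglyceride synthesis. The glucose transporter slc2a2 fell from 976 ± 164 to 123 ± 86.7 CPM (-2.99 ± 0.48) and the growth factor igf1 from 75 ± 36.4 to 12.8 ± 5.34 CPM (-2.54 ± 0.52). Of 7 erythroid genes 4 fell and 1 rose, of 5 thrombocyte and endothelium genes 3 fell, and of 7 hepatocyte genes 3 fell (4 adjusted over the list alone), among them plg, plasminogen (-1.87 ± 0.43). Signal adaptors of pattern recognition rose, with myd88 at 0.84 ± 0.24, traf6 at 0.79 ± 0.22 and irak4 at 2.42 ± 0.57, while tlr2 fell (-2.58 ± 0.74). Of 4 interferon genes dhx58 rose, and irf7 and ifih1 fell. No list passed camera in this comparison, and the smallest adjusted p was 0.135. Summed exocrine pancreas CPM were 5100, 16100 and 14000 in these livers, against 17600 to 33600 in controls. In all 5164 genes were called, 2564 higher and 2600 lower, and leaving out any 1 library gave 3608 to 3971 genes.

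The interaction contrast asked in which genes the combined exposure differed from the sum of both single exposures. In High livers 101 genes passed, 67 above and 34 below additivity; the majority above was not kept by DESeq2 (338 above and 356 below) or without pathogen 2 (138 and 140). The replication genes mcm3 and cdca7 had the pattern of the falls: mcm3 was at 14.3 ± 13.1 CPM with oil, 3.47 ± 4.64 with pathogen and 0.281 ± 0.244 with both, against 0.227 ± 0.102 in controls (-9.42 ± 1.75, adjusted p = 0.0178). The gene cdca7 behaved alike (-8.3 ± 1.54), as did the DNA polymerase subunit pole (-8.98 ± 2.03). Of 18 cell cycle genes 4 fell short of additivity (18 adjusted over the list alone), and the list was lower by camera (median log2 fold change -5.88, adjusted p = 5.52e-14; adjusted p = 0.293 with an estimated correlation). Chaperone (-1.65, adjusted p = 0.0156; 0.556) and sterol synthesis lists (-2.51, adjusted p = 0.0239; 0.591) were lower too, and phagocyte (1.73, adjusted p = 0.000224; 0.293), complement (0.36, adjusted p = 0.00383; 0.293) and lymphocyte lists (1.1, adjusted p = 0.0425; 0.432) higher. The largest excess was seen for rrad (7.49 ± 1.49), cytl1 (6.91 ± 1.17), at 9.54 ± 4.54 CPM with both exposures and 0.222 ± 0.0804 in controls, and gpr4 (4.89 ± 0.93). Without 1 library the count was 21 (control 3), 33 (oil 2), 33 (oil and pathogen 2), 34 (control 1), 35 (pathogen 3), 43 (control 2), 53 (oil 1), 63 (oil 3), 67 (pathogen 1) or 278 (pathogen 2). It was 694 by DESeq2, 160 with only the High livers and 53 with the pancreas covariate, which was chosen after seeing the data.

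In livers of the Low experiment few genes passed. With Low oil 1 gene was called, LOC109629620, which has no symbol; it held 2 counts in both control livers together and 199 in the 3 oil livers (ratio 52.9, 95% counting interval 14.5 to 440, adjusted p = 0.0171). It was also the only gene called in livers given oil and pathogen (ratio 42.8, interval 11.6 to 357, adjusted p = 0.0371). The gene tiparp had 21.7 ± 3 CPM with Low oil against 8.44 ± 0.625 (n = 2) in controls and did not pass (log2 fold change 1.36 ± 0.38, adjusted p = 0.418), and gclm had 1.33 ± 0.35 (adjusted p = 0.387). With Low pathogen 3 genes were called, all lower: gramd4 (-1.7 ± 0.28, adjusted p = 0.0426), LOC109636482 (-1.94 ± 0.25) and LOC109647196 (-2.71 ± 0.41). DESeq2 called these 3 among 102 genes, of which 75 were higher and 27 lower, so most of its calls were higher. Without pathogen 3 these 3 were among 18 called, 6 higher and 12 lower. In 1 of the 3 Low pathogen livers, replicate 2, tnfaip3 was at 203 CPM, against 5.12 and 6.71 in the others, and hamp at 6410 CPM, against 2410 and 122. The summed hepatocyte CPM of that liver was 3920, the lowest of the 23 livers, against 18400 and 10900 in the other Low pathogen livers. The camera test put the cell cycle list higher with Low oil (adjusted p = 1.23e-10), with pathogen (7.35e-07) and with both (5.26e-13), although no member passed by itself; with an estimated correlation the adjusted p were 0.451, 0.803 and 0.449. Sterol synthesis was lower with Low oil (median log2 fold change -2.33, adjusted p = 0.000249; adjusted p = 0.681 with an estimated correlation), and so was the phagocyte list (-1.15, adjusted p = 0.000249; 0.326), while the antioxidant (0.45, adjusted p = 0.00559; 0.326) and cytokine lists (1.41, adjusted p = 0.0236; 0.604) were higher. The cytokine list was higher with Low pathogen (3.21, adjusted p = 0.011; 0.803), with a median of 1.88 when il10, at 0 counts on 1 side, is taken at its bound, and replicate 2 stands apart in that group. Gut members summed to 47.2, 154 and 10.1 CPM in the Low oil livers, against 4.33 and 8.05 in Low controls. With both exposures sterol synthesis (-1.86, adjusted p = 0.0213; 0.673) and phagocyte lists (-0.97, adjusted p = 0.0137; 0.449) were lower, and complement (0.45, adjusted p = 0.0213; 0.449) and antioxidant lists (0.4, adjusted p = 0.0374; 0.449) higher. No interaction gene was called in Low livers (edgeR 0, 793 at an unadjusted p below 0.05; DESeq2 7).

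These Low counts rested on single libraries. The 1 gene called with Low oil was lost without control 1, control 2, oil 1 or oil 2 (0 genes each), and the 1 called with oil and pathogen was lost (0 genes) without any of the 5 libraries of that comparison. The pathogen count was 1 without pathogen 2 and 18 without pathogen 3. Without control 1 it was 2, with 0 of the 3 genes shared, and without control 2 it was 2, with 1 shared. The interaction count was 1 without pathogen 3. With only the Low livers in the fit these 3 comparisons called 0 genes each. DESeq2 called 72, 102 and 58 genes with oil, pathogen and both. RLE scaling gave 2 genes with Low oil, and the pancreas covariate, chosen after seeing the data, gave 0 with both exposures.

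In spleens of High oil fish, 9 of 10 lymphocyte genes and 5 of 7 erythroid genes were lower, and 3 of 6 thrombocyte and endothelium genes higher, than in control spleens. Mitochondrial protein genes took 3.02%, 1.4% and 2.13% of gene reads in these spleens against 0.718%, 0.781% and 0.964% in controls, and oil 1 had 7.47 (in units of 1e6) exon reads, 11% intron reads and 60.2% junction reads, the lowest junction share of the spleens. The B-cell receptor subunit cd79a fell from 187 ± 37.6 to 1.71 ± 0.599 CPM (log2 fold change -6.76 ± 0.8, adjusted p = 0.00014), and cd79b from 157 ± 35.1 to 10.9 ± 1.77 CPM (-3.86 ± 0.65). The B-cell transcription factor pax5 (-6.39 ± 0.95), the B-cell coactivator of octamer factors pou2af1 (-5.39 ± 0.9), the chemokine receptor cxcr5 of follicular B cells (-6.77 ± 0.91) and its ligand cxcl13 (-4.61 ± 1.2) fell too. Of 10 lymphocyte genes 9 fell and none rose (10 fell adjusted over the list alone), with a median log2 fold change of -2.29 (adjusted p = 5.57e-15; adjusted p = 0.0549 with an estimated correlation). Of 7 erythroid genes 5 fell (5 adjusted over the list alone), among them klf1, the erythroid transcription factor (-4.2 ± 0.49), and rhag (-2.72 ± 0.43) (list adjusted p = 1.03e-07; adjusted p = 0.057 with an estimated correlation). Of 6 thrombocyte and endothelium genes 3 rose (3 higher and 1 lower adjusted over the list alone): the endothelial receptors kdr (2.62 ± 0.39) and tie1 (1.88 ± 0.34), and vwf (3.63 ± 0.97), the von Willebrand factor (list adjusted p = 0.0382; adjusted p = 0.412 with an estimated correlation).

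The gene tiparp rose in these spleens from 37.2 ± 3.57 to 390 ± 107 CPM (3.39 ± 0.37, adjusted p = 8.19e-05). The largest rises among genes with a symbol were lgr6 (6.14 ± 0.91), klhl30 (5.9 ± 0.95), the growth factor fgf7 (5.66 ± 1.18), gda (5.63 ± 1.45), which degrades guanine, sost (5.12 ± 0.89), tmtc2 (5.01 ± 0.66), the protease adamts1 (4.86 ± 0.71) and dpp10 (4.79 ± 0.73). Further falls were fam117a (-5.2 ± 0.99), rbp7 (-5.01 ± 0.61) and ppp1r17 (-4.6 ± 0.94). The catalase gene fell and gclc rose (0.75 ± 0.19), the 2 called of 14 antioxidant genes. The cytokine regulators stat3 (1.12 ± 0.23) and socs3 (2 ± 0.5) rose. In pattern recognition tlr2 fell (-3.18 ± 0.54) and mpeg1 rose (2.28 ± 0.44), and ciita, the activator of MHC class II genes, fell (-2.22 ± 0.36). Of 9 phagocyte genes 1 fell, with a list median of -0.03 that turned to the other sign under RLE scaling. The summed phagocyte CPM was 948 ± 138 in these spleens and 1770 ± 456 in controls, with no overlap of libraries. Of 17 chaperone genes atf3 and ddit3 rose (3 adjusted over the list alone; list adjusted p = 0.0382; adjusted p = 0.771 with an estimated correlation). LOC109625128 rose from 8.38 ± 10.5 to 4970 ± 1820 CPM (9.22 ± 1.19). In all 2128 of 18282 genes were called, 1162 higher and 966 lower. Leaving out 1 library gave 1189 (oil 1), 1273 (control 2), 1278 (control 3) and 1404 (oil 3) genes, and the marker covariates and the libraries without gut markers, chosen after seeing the data, gave 2149 and 2399.

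In spleens of High pathogen fish no gene passed (edgeR 0 of 18282, 1424 at an unadjusted p below 0.05; DESeq2 6). The B-cell gene cd79a had a log2 fold change of -0.42 ± 0.62 and hamp was at 356 ± 253 CPM against 174 ± 203 in controls (1.04 ± 1.01, adjusted p = 0.821). The camera test put the cell cycle (median log2 fold change 1.16), sterol synthesis (0.91), chaperone (0.66), complement (5.06), acute phase (4.59), hepatocyte (6.51), carbohydrate (1.25) and exocrine pancreas (0.7) lists higher and the erythroid list lower (-0.66), with adjusted p from 1.61e-09 to 0.0393; with an estimated correlation their adjusted p were 0.273 to 0.466. Complement, acute phase and hepatocyte genes are those of hepatocytes, whose summed hepatocyte marker CPM were 12.8, 1290 and 3.7 in these 3 spleens against 4.46 to 11.6 in controls. Without control 1 the test called 1 gene.

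In spleens of High fish given oil and pathogen, all 10 lymphocyte genes were lower than in control spleens, and 6 of 8 cytokine and 8 of 17 chaperone genes higher. Only the lymphocyte list kept its call with an estimated correlation. Thrombocyte and endothelium members summed to 528, 588 and 304 CPM in these spleens against 184 to 314 in controls, and erythroid members to 449, 330 and 218 against 395 to 1200; neither list passed camera (adjusted p = 0.167 and 0.103). Mitochondrial protein genes took 1.39%, 1.51% and 0.752% of gene reads, against 0.718% to 0.964%. The lymphocyte genes (10 lower adjusted over the list alone; median log2 fold change -3.55) included cd79a (-7.74 ± 0.84), cd79b (-5.38 ± 0.7), the T-cell receptor partner cd3e (-3.71 ± 0.46) and the T-cell kinase lck (-3.38 ± 0.43). This list passed with the preset correlation (adjusted p = 6.78e-17) and with an estimated correlation (adjusted p = 0.0429), the only list call of the 84 in the 22 contrasts that did. The genes cxcr5 and pax5 had 3 counts each in the exposed spleens and were lower by count ratios of 391 (95% counting interval 134 to 1900) and 136 (46.3 to 662). Of 8 cytokine genes 6 rose and 1 fell (6 and 1 adjusted over the list alone), among them il10, an anti-inflammatory cytokine, from 0.127 ± 0.19 to 62.1 ± 67.6 CPM (9.2 ± 1.33, adjusted p = 0.000266), socs3 (3.81 ± 0.54), tnfaip3 (2.64 ± 0.36) and ptgs2 (2.94 ± 0.63) (list adjusted p = 0.000522; adjusted p = 0.222 with an estimated correlation). Of 17 chaperone and stress genes 8 rose and none fell (12 and 2 adjusted over the list alone), among them atf3 (3.08 ± 0.68), ddit3 (1.72 ± 0.28) and hspa5 (2.19 ± 0.59), the main chaperone of the endoplasmic reticulum (list adjusted p = 0.000522; adjusted p = 0.346 with an estimated correlation).

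Of 6 acute phase genes 2 rose (4 adjusted over the list alone) in these spleens, hamp from 174 ± 203 to 3390 ± 673 CPM (4.29 ± 1.15, adjusted p = 0.0143) and the fibrinogen chain fga (6.61 ± 2.12) (list adjusted p = 0.0285; adjusted p = 0.51 with an estimated correlation). Hepatocytes make these proteins, and the summed hepatocyte CPM were 53.9, 16.4 and 25.9 in these spleens against 4.46 to 11.6 in controls. In each High pathogen liver the hepatocyte members summed to more than hamp (9410 to 13600 CPM), while in these spleens hamp lay far above them. Of the Low pathogen livers only liver 2 had hamp above its hepatocyte sum, 3920 CPM, and by far less. These values argue against material of such livers as the source of the hamp rise. Livers given both exposures were not compared, and for fga this was not tested. In High pathogen spleen 2 the hepatocyte members summed to 1290 CPM, and hamp was not called in that group. Of 9 phagocyte genes csf1r (-2.12 ± 0.52) and spi1 (-0.9 ± 0.29) fell (6 adjusted over the list alone; list adjusted p = 0.00591; adjusted p = 0.346 with an estimated correlation). The MHC class II activator ciita (-2.66 ± 0.37) and the invariant chain cd74 (-2.67 ± 0.52) fell, and so did sqle (-3.28 ± 0.47) and fdft1 (-1.85 ± 0.38) of sterol synthesis. The lipid droplet gene plin2 rose (2.96 ± 0.49), as did pfkfb3 (3.32 ± 0.6), tiparp (1.63 ± 0.34) and keap1 (1.08 ± 0.27), and the catalase gene fell. Other large rises were tnfrsf11b, with 3 counts in controls (ratio 357, interval 122 to 1740), lgr6 (6.41 ± 0.92), gda (6.37 ± 1.5), the AP-1 subunit fosl1 (6.07 ± 0.76), the peptide hormone nppc (5.91 ± 1.19) and rrad (5.22 ± 1.18). The gene crispld1 had 0 counts in the exposed spleens and was at least 213-fold lower; pou2af1 (-8.39 ± 1.12), fam117a (-7.85 ± 1.2) and gpa33 (-5.01 ± 1.04) fell. In all 3665 genes were called, 1837 higher and 1828 lower. Leaving out 1 library gave 2160 (oil and pathogen 2), 2268 (control 3) and 2299 (control 2) genes, and the libraries without gut markers, chosen after seeing the data, gave 2773, where the exposed group was 1 spleen taken to vary like the others.

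In High spleens 287 genes departed from additivity, 184 above and 103 below; with RLE scaling 158 were above and 144 below, so the share above was 64.1% and 52.3%. The majority above was not kept by DESeq2 (442 above and 541 below) or without pathogen 1 (105 and 111). The receptor gpr84, found on activated macrophages, was at 12.8 ± 8.55 CPM in controls, 3.85 ± 0.309 with oil, 13.6 ± 5.27 with pathogen and 119 ± 90.7 with both (4.86 ± 0.9, adjusted p = 0.0175). The adrenergic receptor adra2a went the other way, with 15 ± 6.1, 55.7 ± 16.3, 20.2 ± 13.5 and 3.07 ± 0.543 CPM (-4.61 ± 0.77, adjusted p = 0.00936), and hapln3, a protein of the extracellular matrix, likewise (-4.34 ± 1.05). The other named genes were gprc6a (9.53 ± 2.05) and rhobtb3 (4.94 ± 1.2) above and lrrtm1 (-4.84 ± 1.16) below additivity. Of 8 cytokine genes 2 and of 7 erythroid genes 2 lay above, and both lists were higher by camera (adjusted p = 5.36e-05 and 2.9e-07; adjusted p = 0.177 and 0.148 with an estimated correlation). The cell cycle and sterol synthesis lists were lower (medians -1.97 and -1.42, adjusted p = 5.55e-09 and 0.000465; adjusted p = 0.376 for both with an estimated correlation). The count was 41 without oil 1, 59 without pathogen 3, 71 without oil and pathogen 1, 86 without oil 3, 88 without oil and pathogen 2, 91 without pathogen 2, 110 without control 2, 119 without control 3 and 615 without oil 2. DESeq2 called 983 genes, and 132 were called with only the High spleens in the fit.

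In spleens of Low oil fish (n = 2) 30 genes were called, 29 of them higher. Of these 2 spleens, oil 1 had 2.84 (in units of 1e6) exon reads, the fewest of all libraries, 20% intron reads against a spleen median of 4.765%, and gut members at 1530 CPM. They included adamts1 (4.13 ± 0.74, adjusted p = 0.0319), gprc5b (3.73 ± 0.65), lmcd1 (3.67 ± 0.54), fgf13 (3.48 ± 0.54), chad (2.57 ± 0.46), a cartilage matrix protein, the bile acid receptor gpbar1 (2.54 ± 0.36), adamts8 (2.44 ± 0.42) and intu (2.34 ± 0.43), and dapp1 (-2.23 ± 0.42), an adaptor of B-cell receptor signalling, was the 1 that fell. Outside the rule for naming, clu, the chaperone clusterin, rose (1.94 ± 0.28, adjusted p = 0.00713), and LOC109629620 went from 0.186 ± 0.0763 to 53.4 ± 2.45 CPM (8.01 ± 0.68, adjusted p = 2.41e-05). No lymphocyte gene passed over all genes (4 of 10 fell adjusted over the list alone); cd79a was at 15 ± 3.89 CPM against 204 ± 56.5. That list was lower by camera (median -0.97, adjusted p = 3.31e-06; adjusted p = 0.464 with an estimated correlation), as was the phagocyte list (-0.7, adjusted p = 0.0361; 0.597), and the thrombocyte and endothelium list was higher (1.12, adjusted p = 0.0361; 0.464). The gene tiparp was at 56.9 ± 9.46 against 19.5 ± 4.77 CPM (1.54 ± 0.37, adjusted p = 0.107). Without 1 library the count was 3 (control 3), 4 (control 2), 6 (oil 2), 12 (oil 1) or 13 (control 1), where a group left with 1 spleen was taken to vary like the others. DESeq2 called 485 genes, and 2 were called with only the Low spleens.

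With Low pathogen (n = 2) no spleen gene passed (edgeR 0, 2235 at an unadjusted p below 0.05; DESeq2 155). The cytokine list was higher by camera (median log2 fold change 1.57, adjusted p = 0.000153; adjusted p = 0.297 with an estimated correlation), with no member called over all genes and 6 of 8 adjusted over the list alone. These 2 spleens held gut members at 3850 and 147 CPM, against 6.19 to 15.8 in Low controls, and lymphocyte members at 204 and 847, against 677 to 782. Erythroid, cell cycle and chaperone lists were also higher (medians 1.02, 1.02 and 0.67, adjusted p = 0.0112, 0.0155 and 0.0236; adjusted p = 0.649 for all 3 with an estimated correlation). Without pathogen 2 the test called 96 genes, and with the marker covariates 1. With Low oil and pathogen 8 spleen genes were called, all higher, among them clu (1.72 ± 0.26, adjusted p = 0.0146), LOC109629620 (6.64 ± 0.64) and LOC109633099 (3 ± 0.35). Antigen presentation, lymphocyte and phagocyte lists were lower by camera (adjusted p = 0.0165, 6.68e-05 and 0.00568; adjusted p = 0.398 for all 3 with an estimated correlation). In the Low spleens given both, gut members summed to 6.9, 11.4 and 2770 CPM, against 6.19 to 15.8 in Low controls. Exocrine pancreas members summed there to 79500, 172000 and 5370 CPM, against 54.6 to 135000. That count of 8 was 2 without control 1 or control 2, 3 without control 3, 4 without oil and pathogen 2 and 5 without oil and pathogen 1. It was 290 by DESeq2, 2 with only the Low spleens and 4 with the marker covariates, chosen after seeing the data. No interaction gene was called in Low spleens (edgeR 0, 1422 at an unadjusted p below 0.05; DESeq2 75), and 17 were without pathogen 2.

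**Figure D2:**
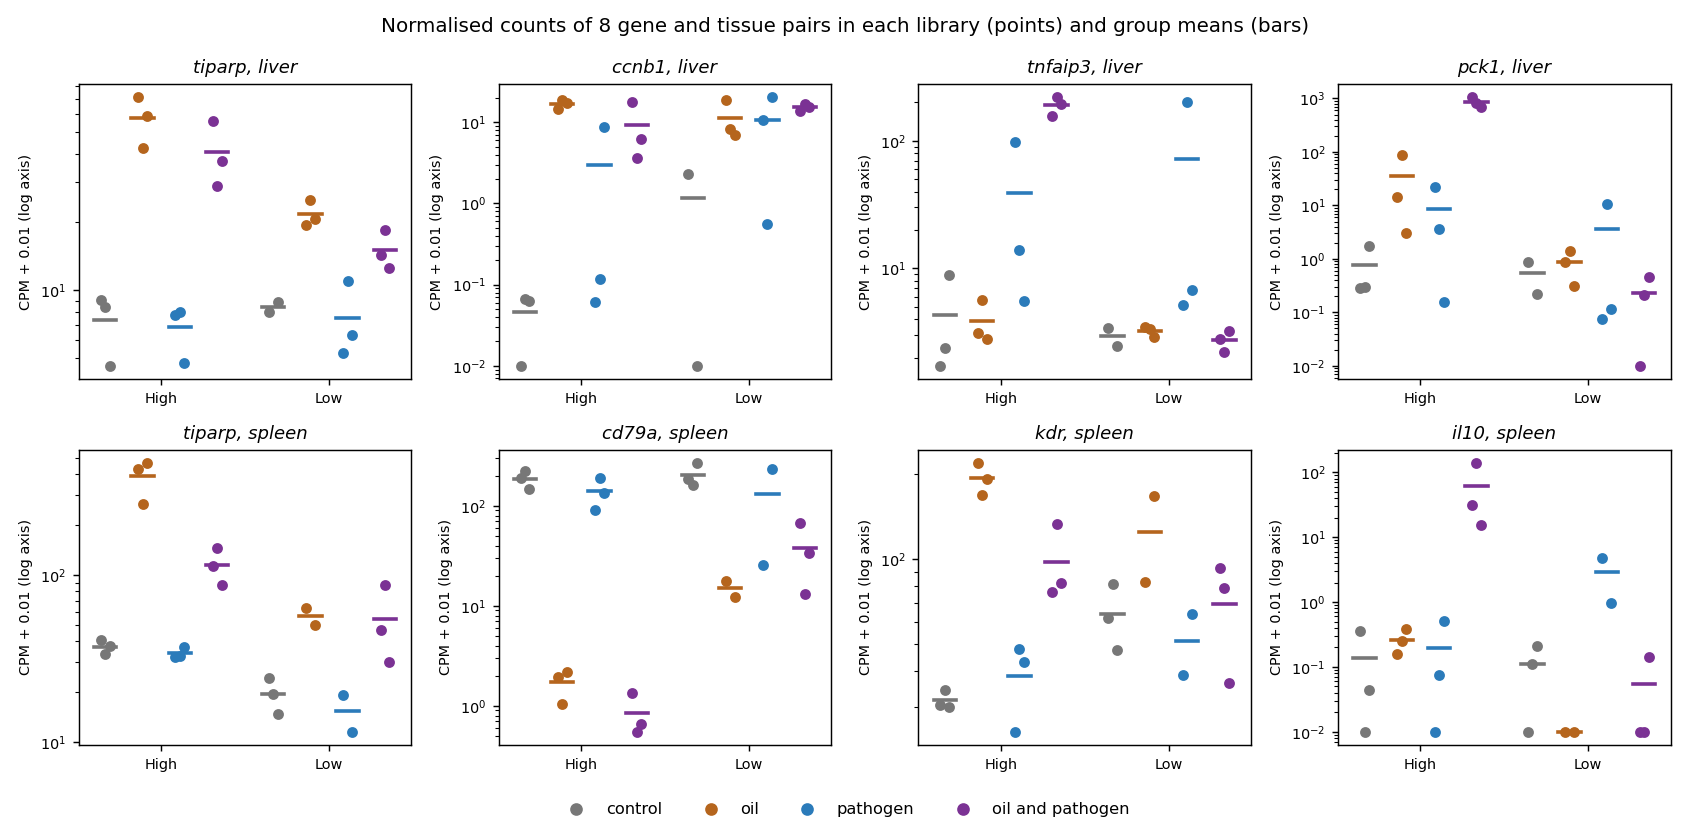
CPM (with 0.01 added, log axis) of genes named in the text in each library (points) with group means (bars), for High and Low experiments. In High spleens cd79a was at 187 CPM on average in controls and at 1.71 with oil, and il10 rose with both exposures to a mean of 62.1 CPM.

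The effect of the combined exposure differed between the High and Low experiments in 700 liver genes (296 more positive and 404 more negative in High) and 522 spleen genes (268 and 254). In the liver pck1 was at 0.217 ± 0.227 CPM in Low fish given both exposures and 0.53 ± 0.455 (n = 2) in Low controls (difference of log2 fold changes 11.36 ± 2.79, adjusted p = 0.0327), and atf3 was at 1.48 ± 0.639 and 6.34 ± 7.59 CPM (9.41 ± 2.12, adjusted p = 0.0253). The gene arf4 had the largest difference (13.53 ± 2.87), and ubap1l (-7.92 ± 1.92), hsf2bp (-7.69 ± 2.14) and fam117a (-7.24 ± 1.72) the most negative. In the spleen il10 (9.97 ± 2.53), slc4a10 (14.12 ± 3.01) and mylpf, a muscle protein (10.81 ± 2.76), were more positive in High, and crispld1 (-8.27 ± 2.08), cxcr5 (-6.15 ± 1.23) and pou2af1 (-6.04 ± 1.3) more negative. For mylpf the effect in High spleens given both turned from 5.68 to -1.35 (adjusted p = 0.681) without the libraries with gut markers, which left 1 exposed spleen. Of 10 lymphocyte genes 6 fell further in High spleens (median -2.89, adjusted p = 1.44e-12; adjusted p = 0.116 with an estimated correlation). There the cytokine and chaperone lists were more positive in High (1.24 and 1.12, adjusted p = 0.000619 and 1.29e-05; adjusted p = 0.187 for both with an estimated correlation). For oil alone and pathogen alone no gene differed by edgeR: liver oil 0 (1374 at an unadjusted p below 0.05; DESeq2 34), liver pathogen 0 (687; DESeq2 1), spleen oil 0 (2384; DESeq2 257) and spleen pathogen 0 (1807; DESeq2 67). The labels give the High experiment more oil and more bacteria together, so these differences cannot be assigned to either.

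Single libraries moved these counts. The liver count of 700 was 6 (5 more positive and 1 more negative) without Low control 1, 69 (50 and 19) without Low control 2, 114 and 405 without Low oil and pathogen 1 and 2, 116, 289 and 339 without High controls 2, 1 and 3, and 188 and 283 without High oil and pathogen 2 and 3. The spleen count of 522 was 189 without High oil and pathogen 2, 205 and 300 without Low oil and pathogen 1 and 2, 228 and 237 without Low controls 2 and 3, and 246 and 230 without High controls 2 and 3. With the replicate number as a block the counts were 121 and 443, and DESeq2 called 1675 and 1375 genes. For oil alone, 1 liver gene was called without High oil 1 or High oil 2, 23 spleen genes without High control 1 and 6 without High oil 2; the marker covariates gave 4 and the libraries without gut markers 76 in the spleen, both chosen after seeing the data, and the latter left 1 Low oil spleen. For pathogen alone 3 spleen genes were called without Low pathogen 2.

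The response to High oil differed between the tissues in 1101 of 18856 genes, 211 more positive in the liver and 890 in the spleen, and that to High oil and pathogen in 1378 (488 and 890). With oil the cell cycle gene cdc20 (difference of log2 fold changes, liver minus spleen, 5.65 ± 1.58, adjusted p = 0.0272) and gclm (2.22 ± 0.5, adjusted p = 0.00586) were more positive in the liver, and kdr (-2.8 ± 0.45, adjusted p = 0.000259), tie1 (-3.33 ± 0.46, adjusted p = 4.34e-05) and adamts1 (-3.95 ± 0.77, adjusted p = 0.00166) in the spleen. The gene tiparp did not pass (-0.56 ± 0.47, adjusted p = 0.533). The thrombocyte and endothelium list was more positive in the spleen (adjusted p = 4.37e-05; adjusted p = 0.0352 with an estimated correlation), and the cell cycle list in the liver (adjusted p = 2.63e-11; adjusted p = 0.305 with an estimated correlation). With both exposures cd79a was less negative in the liver (6.76 ± 1.28, adjusted p = 0.00127). Liver cd79a was low, with 68 counts in all High control livers together. Its partner cd79b had no counts in High livers given both and was at least 27.5-fold lower there.

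Comparisons that share controls share their chance values, so overlaps were set beside values simulated with unchanged groups and the same controls. In High livers 616 genes were higher and 727 lower with oil and with both exposures, where independence would give 149 and 159; 9 were called in opposite directions. Across genes the log2 fold changes had r = 0.69 and a covariance of 1.52, against 0.52 and 0.21 in the simulation. Pairs with pathogen alone, which called 0 genes, also exceeded the simulated covariance in these livers. It was 0.64 against 0.21 for oil and pathogen, and 0.78 against 0.2 for pathogen and both. An excess was thus not particular to pairs that share oil. In High spleens 578 were higher and 609 lower in both (117 and 96.6 under independence) and 20 were opposite. There r was 0.5 against 0.48 in the simulation, and the covariance 0.96 against 0.34. For oil and pathogen in High spleens the covariance was 0.31 against 0.34, and for pathogen and both 0.64 against 0.34. Unchanged groups gave no calls in the simulation, so the shared calls have no simulated value to be set against. Genes are not independent replicates in these values.

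**Figure D3:**
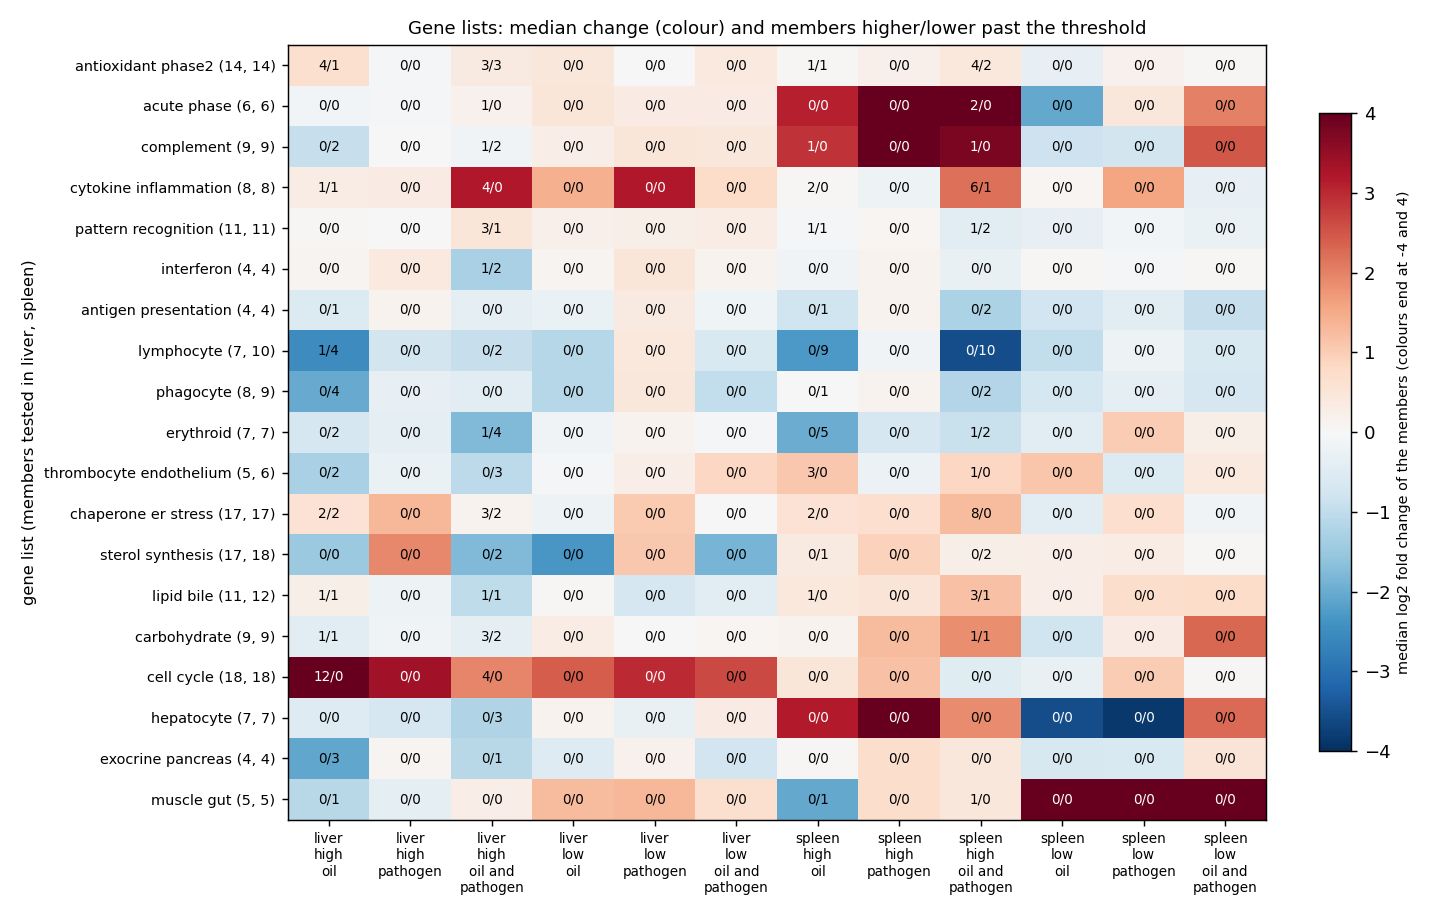
Median log2 fold change of each gene list (colour) in the 12 comparisons with controls, with the number of members called higher and lower. In High spleens the lymphocyte list had 9 of 10 members lower with oil and 10 of 10 with both exposures, and in High livers the cell cycle list had 12 of 18 higher with oil.

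Markers of other organs differed between libraries. The gut members fabp2, cdh17 and slc15a1 summed to over 100 CPM in 8 of the 22 spleen libraries, with a median of 24.05 and a highest value of 3850 CPM in Low pathogen spleen 1. Hepatocyte members summed to 1290 CPM in High pathogen spleen 2 and 631 in Low oil and pathogen spleen 2. Exocrine pancreas members summed to 54.6 to 135000 CPM in the 3 Low control spleens alone. Lymphocyte members summed to 686 to 744 CPM in High control spleens, 113 to 139 with oil and 69.1 to 107 with both exposures. In the spleens 3 of the 4 libraries with the highest gut values were of exposed Low fish.

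**Figure D4:**
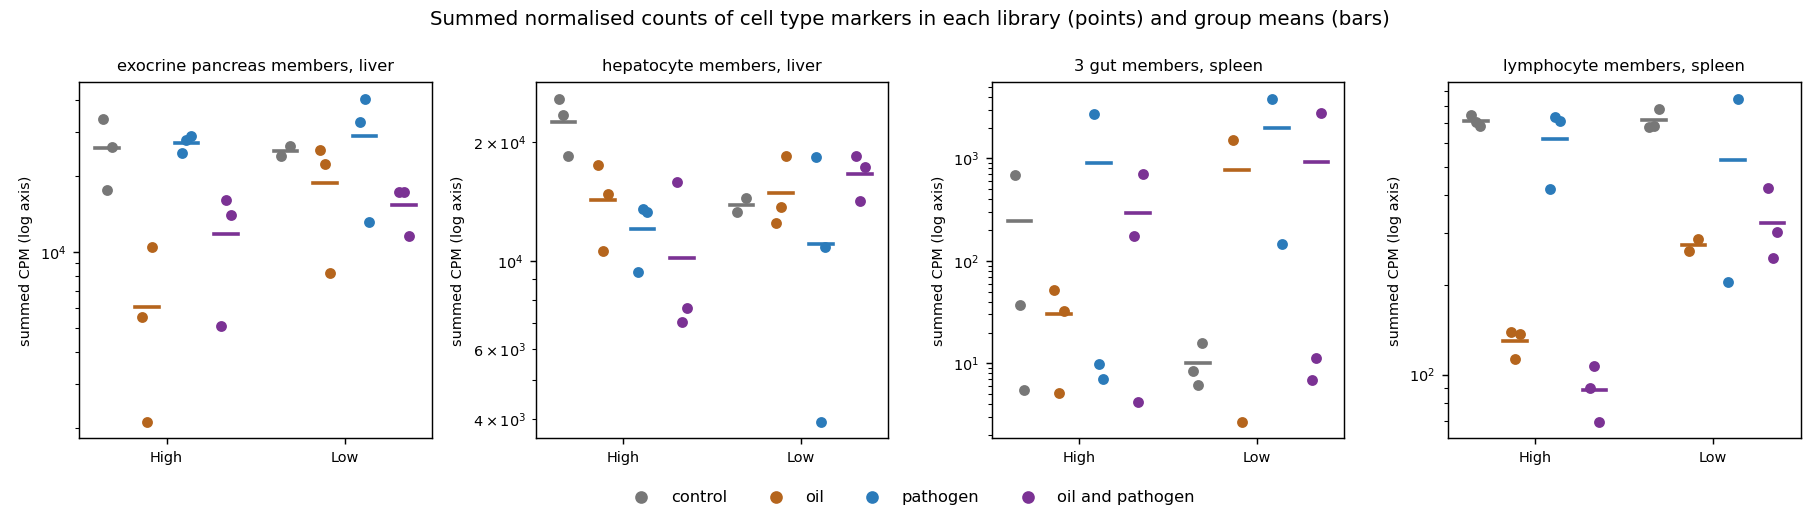
Summed CPM (log axis) of marker genes in each library (points) with group means (bars), for liver and spleen and for High and Low experiments. Exocrine pancreas members ran from 17600 to 33600 CPM in High control livers and from 2110 to 10500 with oil, and lymphocyte members in High oil spleens lay below all High control spleens.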

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

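Chosen after the result was seen were the tests of a general loss of spleen transcripts and of the scaling on the lymphocyte genes, both tests of Low pathogen liver 2 and the test of the pancreas genes. The marker covariates behind the first lymphocyte test below were also chosen after seeing the data. The scaling test replaced one by RLE scaling, which left the list as low but moved all genes by only 0.031 and so decided nothing.

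The departure from additivity with both exposures differed between groups in 101 liver genes and 287 spleen genes of the High experiment. In the liver 5 of 100 splits of the same 12 samples called as many genes, so chance was not excluded. The highest other split called 1011, far over the real count, which points to a structure of the samples. The exposures to oil may be that structure, since 1945 genes were called with oil and 5164 with both, against 0 with pathogen alone. Which samples that split joined was not examined. In the spleen 3 of 100 splits did, a share under 0.05, with a highest other of 504, above the real count. The splits of both tissues shuffled labels over all groups, so they stand for no effect of any exposure, not for additive effects. They therefore cannot decide whether chance gave the departures from additivity. Without single libraries the counts ran from 21 to 278 and from 41 to 615.

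The effect of both exposures differed between the High and Low experiments in 700 liver genes and 522 spleen genes. For the spleen 1 of 100 splits, the real one, called as many, with a highest other of 471. These splits shuffled the exposed and control labels of both experiments, so they stand for no effect at all, not for equal effects. They therefore cannot decide whether chance gave the difference between the experiments. The liver contrast has a control group of 2, and no split was run. The liver count was 6 without Low control 1, with a range from 6 to 718 without single libraries, and 121 with the replicate number as a block. Dose of oil, dose of bacteria and experiment vary together in this contrast.

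The effect of High oil differed between liver and spleen in 1101 genes, and that of High oil and pathogen in 1378. These genes were found by a test of the difference itself. Since the spleen files count no exons for 1552 genes, those genes are outside it. Whether the tissues came from the same fish is not stated.

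Long noncoding RNA genes without exons in the spleen files were outside the main measurement and were tested by total gene reads, which include introns. Of 412 tested, 26 differed from controls with High oil (19 higher and 7 lower), 40 with High oil and pathogen (25 and 15) and 1 with Low oil (1 and 0). Whether these reads belong to overlapping genes was not tested.

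The lower lymphocyte genes in spleens of High oil fish were weighed against 3 technical explanations. With gut, hepatocyte and pancreas scores as covariates the median log2 fold change was -2.17 (median SE 0.43), which argues against material of other organs. The thrombocyte and endothelium list lay 3.36 above the lymphocyte list (sum of median SEs 0.87). This test was chosen after the result was seen, and it shows only that both lists were not lowered alike. A wider loss of blood cell transcripts stays open, since erythroid members summed to 131 ± 55.3 CPM with oil and 757 ± 408 in controls. The lymphocyte list lay -2.26 from the median of all genes (median SE 0.43). A scaling factor moves both alike, which argues against the TMM scaling. RNA quality stays open and was not tested: mitochondrial protein genes took 1.4% to 3.02% of gene reads with oil and 0.718% to 0.964% in controls. That share did not follow the lymphocyte members in other spleens. Low controls had 1.4%, 2.61% and 2.35% with lymphocyte sums of 677, 686 and 782 CPM. High oil and pathogen spleen 3 had 0.752% with a sum of 69.1 CPM. Fewer lymphocytes and lower expression per cell stay open too. A larger endothelial share as the whole cause would lower phagocyte genes alike, and their values were looked at after the result was seen. The median of that list was -0.03 (median SE 0.42). The summed phagocyte CPM was nevertheless lower, at 799 to 1070 with oil and 1260 to 2140 in controls. Lymphocyte members summed to 113 to 139 CPM with oil and 686 to 744 in controls, a larger fall. By either measure phagocyte genes were thus not lowered like lymphocyte genes. These values argue against a larger endothelial share as the whole cause of the lymphocyte fall. A part in it stays open, since the erythroid members also fell widely.

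Low pathogen liver 2 stood apart from the other Low pathogen livers, with tnfaip3 at 203 CPM against 5.12 and 6.71. A first test of a mislabelled oil liver by tiparp went with that explanation, since its 11 CPM lay above the highest other liver without oil (9.01), although below the lowest liver with oil (12.5). It was replaced by LOC109629620, which was at 0 CPM in this liver, at most 0.145 in the other livers without oil and at least 2.37 in livers with oil, and which argues against that explanation. A first test of pancreas or gut material also went with its explanation (40600 CPM against 33600 in the highest other liver), and a second left it open (log2 ratio 0.27, SD 0.41). Both were replaced, after their outcomes were seen, by the hepatocyte members, which added material would dilute alike: their log2 ratios to the other Low pathogen livers spanned 6.65, against 1.12 between those livers, which argues against such material as the whole cause; a stronger infection and other states of this liver stay open as untested.

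The exocrine pancreas genes were lower in High oil livers, and their log2 fold changes spanned 0.73 with a largest SE of 0.58. A smaller share of pancreatic tissue, which in many fishes lies within the liver, would lower the members alike. The test was lenient, because the SE holds the spread of pancreas content between livers, which the members can share. It therefore does not decide for that explanation. Lower expression in the same number of pancreatic cells stays open, since it could lower the members alike. With the pancreas score as a covariate, chosen after seeing the data, the High oil liver count fell to 57, in a comparison whose groups the summed pancreas CPM parts by itself (at least 17600 in controls and at most 10500 with oil). The liver count of 1945 was 504 without oil 2.

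The splits of 3 against 3 are too few for a share under 0.05. In High livers the real and the highest other counts were 1945 and 0 with oil, 0 and 0 with pathogen (edgeR; 1803 genes at an unadjusted p below 0.05, DESeq2 284) and 5164 and 0 with both. In High spleens they were 2128 and 0, 0 and 0 (edgeR; 1424 genes, DESeq2 6) and 3665 and 0. In Low spleens given both they were 8 and 1. As many genes as the real split were called in 1 of 10 splits each, and in 10 of 10 for pathogen.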

How the results depend on the processing

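Marker covariates and the libraries without gut markers were chosen after seeing the data; the other alternatives were planned. Those for normalized values did not apply to counts. Where a setting moved a result, the cause was not tested. DESeq2 called 3076 liver genes with High oil, 284 with High pathogen, 694 in the High interaction, 72, 102 and 58 with Low oil, pathogen and both, 7 in the Low interaction, and 34, 1 and 1675 in the High minus Low differences for oil, pathogen and both. In the spleen it called 6 with High pathogen, 983 in the High interaction, 485, 155 and 290 with Low oil, pathogen and both, 75 in the Low interaction, and 257, 67 and 1375 in the differences. RLE scaling gave 2 liver genes with Low oil, and no count filter 1 with High pathogen.

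The labels do not say what the replicate number means. The replicate number as a block gave 1279 liver genes with High oil, 41 in the High interaction, 5 with Low oil, 0 with Low oil and pathogen, 2 in the oil difference, 121 in the combined difference and 7 spleen genes with Low oil. Only samples of the same experiment gave 2 liver genes with High pathogen, 160 in the High interaction, 0 each with Low oil, pathogen and both, and in the spleen 132 in the High interaction, 2 with Low oil and 2 with Low oil and pathogen; fewer samples enter that fit. Marker covariates gave 57 liver genes with High oil, 53 in the interaction, 0 with Low oil and pathogen, and in the spleen 1 with Low pathogen, 4 with Low oil and pathogen and 4 in the oil difference. Libraries without gut markers gave 76 in the spleen oil difference, where 1 Low oil spleen was left, and no value where a group was lost (Low pathogen, its interaction and its difference).

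Without 1 library, liver counts ran from 504 to 1510 with High oil, 0 to 4 with pathogen, 3608 to 3971 with both, 21 to 278 in the interaction, 0 to 1 with Low oil, 1 to 18 with Low pathogen, 0 to 0 with both, 0 to 1 in the Low interaction, and 0 to 1, 0 to 0 and 6 to 718 in the differences for oil, pathogen and both. Spleen counts ran from 1189 to 1855, 0 to 1, 2160 to 3496, 41 to 615, 3 to 13, 0 to 96, 2 to 11, 0 to 17, and 0 to 23, 0 to 3 and 189 to 755 in the same order. A group left with 1 library was taken to vary like the others.

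Among named genes edgeR made 264 calls and DESeq2 403, of which 262 were shared. Of 84 list calls 1 held with an estimated correlation, and 75 were among the 82 made with a block. The muscle gene mylpf turned from 5.68 to -1.35 (adjusted p 0.681) in High spleens given both when libraries with gut markers were left out, which left 1 exposed spleen. Depth limits low genes: 3 counts are up to 0.21 CPM in the liver and 1.06 in the spleen. Whether replicate numbers pair samples was not settled: the median correlation of samples with the same number was -0.01 in High livers, 0 in Low livers, 0.01 in High spleens and 0.1 in Low spleens, against 0.01, -0.01, -0.06 and -0.09 for different numbers, with ranges from -0.61 to 0.55 and from -0.62 to 0.61.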

Other observations

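The lists of genes called in the High experiment were tested in the Low experiment, which shares no library with it, with tests written before the result was seen; the use of an estimated correlation beside the preset one was added after.

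The hypothesis that the lower oil dose moves the same genes the same way went with the tests in both tissues. In Low oil livers 85.1% of the 948 genes higher with High oil were higher and 90.5% of the 997 lower were lower (camera p 2.94e-26 and 6.75e-36; with an estimated correlation 0.0132 and 0.00648). In Low oil spleens the shares were 85% of 1162 and 79.5% of 966 (p 1.78e-30 and 2.64e-19; 0.006 and 0.00618). Without single libraries these shares lay between 74% and 90%. A common response may therefore be present below the threshold in Low oil fish, in which 1 liver gene and 30 spleen genes were called. It may not be particular to oil, since the High oil lists were not tested in Low pathogen fish. In Low spleens the log2 fold changes with oil and with pathogen had r = 0.72 and a covariance of 1.76. Unchanged groups with the same controls gave 0.37 and 0.35 in the simulation. In Low livers r was 0.47 against 0.63, and the covariance 0.47 against 0.32.

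The hypothesis that the pathogen alone moves genes called with both exposures and not with oil was tested in Low pathogen fish. In the spleen 80.1% of 1249 and 78.2% of 1209 genes went the same way (p 3.56e-14 and 1.79e-19; with an estimated correlation 0.0425 and 0.0344), but 64.1% and 63.4% without Low pathogen spleen 1, whose gut members were at 3850 CPM, so part of the shares in the spleen rests on that library. In the liver 80.5% of 1941 and 74.1% of 1871 did, and met the criterion written before (p 5.76e-14 and 1.63e-16), but with an estimated correlation p was 0.122 and 0.109. Without Low pathogen liver 2 the liver shares were 53.2% and 51%, so they rest on that liver. The hypothesis stays open in both tissues.

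LOC109629620, chosen after its values were seen, was called in every comparison of an oil-exposed group with its controls, with log2 fold changes of 8.63 ± 0.65 in High oil spleens, 6.7 in High spleens given both, 8.01 ± 0.68 and 6.64 ± 0.64 in Low spleens, and count ratios of 294, 127, 52.9 and 42.8 in the livers. In Low livers these calls were fragile: with oil it was not called with only the Low samples or without any of 4 of the 5 libraries, and with both not with a block, only the Low samples, the marker covariates (chosen after seeing the data) or without any 1 library. With pathogen alone it was called in none of the 4 comparisons, with log2 fold changes from -1.4 to 0.53.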
